A study of Mus musculus with 2 samples.

How the data were processed

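The series holds 2 iCLIP samples of mouse embryonic stem cells, 1 with FLAG-HA-tagged human Ago2 and 1 with untagged human Ago2 as control. Files analysed here belong to the tagged library; the untagged library enters through the authors' enrichment values alone. The submitters' processing notes name Bowtie and TopHat and the builds mm9 and NCBIM37, without versions or roles. The cluster caller, the source of the expression values and the ranking of microRNAs are not given in the sources used here.

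The cluster list has 6211 enriched clusters at the authors' threshold of p under 0.05. Its peak height is a signal in whole reads, not normalized, per the file headers. The deposited score joins tagged reads, log2 enrichment over the untagged library and a binomial p, and it is treated as other text. The authors' log2 was matched within 0.005 in all 6211 clusters by tagged reads plus 1 over an untagged whole number plus 1, and their p within 0.0001 by a binomial test with probability 0.5. That number is used as the untagged count. It was 2 in 134 clusters, 4 in 36 and 3 in 0. This gap argues against a raw count, and how the number was scaled is open. The crosslink column holds positions with most crosslink events and their number, other text per the file headers.

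The site table lists seed matches of the 50 microRNA seeds and further 8mers, used here as control, in transcripts of at least 0.1 FPKM. Coverage per site is in rpm, reads scaled to library size, made by the authors. All 1641948 entries (100%) were whole multiples of 1.27 rpm within 0.001, so whole reads of 789000 were recovered. Isoform expression is FPKM as computed by the authors. The deposited log2 coverage is a log2 value that was matched by log2 of rpm minus 0.24 times log2 of FPKM with a constant of -1.69. PhastCons is a conservation score from 0 to 1 per the file headers. Reads were present at 152190 entries (9.27%), with up to 351 at a site.

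Sites were made distinct by position, strand and sequence, which removed 22927 repeats. Left out were 12225 7mers and 25025 6mers inside a longer match, and 170165 control 8mers overlapping a site of a listed seed. This left 1411606 sites in 15267 genes, 687523 of listed seeds and 724083 control. The 50 7mers fall into 48 families that share a 6mer. The 966 8mers that extend none of the 50 7mers served as control, a division recognised after the data were examined, since the file does not name it. This set holds the let-7 match CTACCTCA, so it is not free of microRNA seed matches, and values over control are relative to it. MicroRNA names were given by textbook seed sequence only. Support was at least 1 read at the site. Observed over expected support divides supported sites by the number given by control 8mers in the same region and the same stratum of 0.5 log2 FPKM. Shares have exact (Clopper-Pearson) 95% binomial intervals, and ratios have intervals from 1000 draws of whole genes. The smallest cluster held 5 reads. Folds against 0 untagged reads use a floor of 3 counts per cluster, and none are given for sums over several clusters. Sites and genes are not replicates, so no p was made from them.

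Overlap with clusters meant at least 1 nt on the same strand. For it, 216 clusters across splice junctions and 2 wider than 200 nt were left out, leaving 5993. Background came from sites displaced in genome coordinates by 100 to 500 nt in steps of 100 in each direction, 10 displacements in all. Of 320 symbols in 14 gene lists, 291 matched the site table (273 distinct genes). The share of each list with a cluster was set against 10000 random lists of equal size in the same 10 FPKM deciles, and a list was called when it lay outside their central 95%. Target lists are from textbook knowledge. Symbols were taken from the files. The reference annotation, on another assembly, served for the spelling of names and gave no coordinates. Coordinates are 1-based on mm9.

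The comparisons, gene lists, rule for named genes and the first set of alternatives were chosen before the data were examined. Genes and families named are the 15 genes with the most clusters over a 7mer or 8mer, the 10 clusters with the lowest p, the 10 families with the most supported sites, the 5 with the highest and 5 with the lowest share among those with at least 100 sites, and in each list up to 4 members with the most clusters and up to 4 of the highest expression without one. A few genes that this rule names are left out of the text. Alternatives tried were cluster overlap in several forms in place of reads, stricter p, higher FPKM minimums, 3' UTR sites alone, every entry as listed, subsets of match types and families, merged clusters and other matching of random lists. Added after seeing the data were other control sets, nested matches kept, at least 2 reads, match types compared within families (supported 8mers over the number given by the 7mer support of each family), Benjamini-Hochberg adjustment of the authors' p, mitochondrial clusters left out, families at positions that share no base, and matching on FPKM and 3' UTR sites.

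The methods were tested on simulated data. With planted folds of 2, 1.5 and 1.2 over the 1411606 sites, 20 simulations recovered means of 2.00, 1.50 and 1.20, and the intervals held the fold in 18, 18 and 19 of 20. Of 50 lists of 20 random genes, 2 were called high, and of 50 lists with a planted 3-fold excess, all 50 were. The simulated chance of a cluster depended on the FPKM decile alone. These lists therefore do not test the calls where clusters also depend on other traits, such as 3' UTR sites, or for lists of other sizes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.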

Results

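RNA bound by Ago2, the Argonaute protein that carries microRNAs to their targets, was mapped by iCLIP, in which proteins are crosslinked to RNA in living cells and the RNA fragments they hold are sequenced. Per the series description, the mouse embryonic stem cells carried human Ago2 under doxycycline control as their single Argonaute protein, either with a FLAG-HA tag or without a tag. Both cell lines were kept in 0.1 µg/mL doxycycline and induced with 2.5 µg/mL for 24 h. The design held 1 library per group, so no spread between replicates could be measured. Intervals cover counting error (exact binomial) or the resampling of genes, and nothing else. Whether duplicate reads were removed through molecular identifiers was not examined, so reads are not taken as independent molecules. The values per predicted site rested on 789000 reads of the tagged library, and the depth of the untagged library is not given in the sources used here. Untagged numbers are those implied by the authors' enrichment values, and their scaling to the tagged library is unknown.

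The tagged library against the untagged one showed where Ago2 sat on RNA. Most Ago2 clusters lay in messenger RNA, and 3806 of 6211 (61.3%, exact 95% interval 60.1 to 62.5) were in 3' UTRs, the usual place of microRNA sites. Coding sequence held 991 clusters (16%, 15.1 to 16.9), introns 316 (5.09%) and 5' UTRs 99 (1.59%). A further 447 (7.20%) were annotated as intergenic, 177 (2.85%) as antisense to a gene, 50 (0.805%) as long noncoding RNA and 39 (0.628%) as histone genes. Clusters held 59410 tagged reads, 7.53% of the 789000, against 1541 untagged. No untagged read was implied for 5316 clusters (85.6%), a share partly set by the authors' threshold, which clusters of 5 or 6 reads pass only against 0. Among the 3483 clusters of at least 7 reads it was 74.3% in all, 81.3% in 3' UTRs, 77.7% in coding sequence, 35.4% in intergenic clusters and 32.6% in antisense clusters. The median cluster was 42 nt wide (interquartile range 35 to 52) and held 7 tagged reads (5 to 10). At the low end, 1720 clusters (27.7%) held 5 tagged reads and no untagged one, or p = 0.03125 in the authors' binomial test, which compares the reads of 2 libraries and not replicated conditions. With p under 0.01, 3081 clusters remained, 68.3% of them in 3' UTRs.

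The cluster with the lowest authors' p was in the 3' UTR of Fgf4, a growth factor secreted by embryonic stem cells, on mm9 chromosome 7 from 152050686 to 152050939, with 305 tagged reads against 25 untagged (12.2-fold, p = 1.16e-62 in the authors' exact binomial test). Txnip, the thioredoxin-interacting protein, had a 3' UTR cluster on chromosome 3 from 96364933 to 96365760, with 234 reads against 14 (16.7-fold). In the 3' UTR of Aebp2, a partner of Polycomb repressive complex 2, 94 tagged reads against 1 untagged covered chromosome 6 from 140601088 to 140601226, over the seed matches AGCACTT, GTTTGAGA and TTGCCAAA. The 3' UTR of Unk, which encodes an RNA-binding zinc finger protein, held 81 reads against 0 (at least 27-fold) on chromosome 11 from 115921930 to 115922007, over AATCCCTA and CTTTGAT. Tmem55b had 77 against 0 (at least 25.7-fold) on chromosome 14 from 51547135 to 51547233, over the 8mer TGCTGCTA. For Tbx3, a T-box transcription factor, the counts were 85 against 1 on chromosome 5 from 120133861 to 120133967, over GGCAGCTA. Gpt2, an alanine aminotransferase, had 86 against 2 on chromosome 8 from 88049593 to 88049730, and Csnk1a1, casein kinase 1 alpha, 82 against 1 on chromosome 18 from 61749090 to 61749257. Outside 3' UTRs, an intergenic cluster across a splice junction on chromosome 12 from 110894052 to 110895030 held 129 reads against 6 (21.5-fold). A cluster downstream of 4921513D23Rik on chromosome 16 from 14109933 to 14110075 held 109 against 7 (15.6-fold).

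Some genes had many clusters over a 7mer or 8mer seed match. Mcl1, an anti-apoptotic member of the Bcl2 family, had 17 clusters, 8 of them over such a match, with 240 tagged reads against 4 untagged. Btg2, an antiproliferative gene, had 11 clusters, 8 over a match, and Cnot6, a subunit of the main deadenylase complex, had 12 and 7. The kinase genes Sik1 and Pim3 had 10 and 16 clusters, with 165 reads against 2 and 153 against 1. The transcription factor gene Sp1 had 10 clusters with 91 reads against 0. D730040F13Rik led with 9 clusters over a match among 12, and with 140 reads against 0. Aebp2 had 14 clusters (232 reads against 2), 4933426M11Rik 14 (191 against 1), 9530068E07Rik 10 (132 against 0), and Luzp1 and Zfp568 6 each (98 against 2 and 49 against 0). The noncoding linc444 stood apart in its background, with 130 reads against 15. Clusters carried 2830 gene names, of which 2613 matched the 15271 genes with predicted sites (17.1%). Of these 2613, 230 had at least 5 clusters and 1473 had 1. Genes with a cluster had a median listed expression of 13.9 FPKM, against 3.26 FPKM for genes without.

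The gene lists, fixed before the data were examined, asked which groups of stem cell transcripts Ago2 occupied, each against random lists from the same FPKM deciles. Of 25 pluripotency factors, 16 (64.0%, 42.5 to 82.0) had at least 1 cluster, against a mean of 27.6% for 10000 random lists (2.32 times). Fgf4 had 20 clusters (503 tagged reads against 26 untagged), Tfcp2l1 10 (94 against 0), Klf2 8 (182 against 5) and Nanog 7 (56 against 0). A listed 7mer or 8mer was overlapped by 1 cluster each of Fgf4, Tfcp2l1 and Klf2 and by 0 of Nanog. Clusters over such a match were present in 9 of the 25 factors, so a cluster alone does not show a listed microRNA site. Pou5f1, Zfp42, Tdgf1 and Dppa2 had none, although Pou5f1 was listed at 609 FPKM. Genes of the microRNA pathway and of messenger RNA decay had clusters in 16 of 29 (55.2%, 35.7 to 73.6, against 24.3%). Among them were Trim71, a stem cell ubiquitin ligase, with 13 clusters (106 reads against 0, 1 of the 13 in the 3' UTR), Tnrc6b with 10 (109 against 3) and Tnrc6a with 8 (90 against 0), both of which encode GW182 partners of Argonaute. Drosha, Xpo5 and Tarbp2, which act in microRNA maturation, and Lsm14a had none.

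Targets listed for the stem cell microRNAs with the AAGUGC seed had the highest share, 13 of 19 (68.4%, 43.4 to 87.4, against 19.8%, 3.45 times). The cell cycle inhibitor Cdkn1a had 16 clusters (199 reads against 4), the pocket protein gene Rbl2 7 (103 against 0), and Cdc25a and E2f1 5 each (30 and 41 reads against 0). No cluster was listed for Lefty2, Rhoc or Mbd2. A 7mer or 8mer of this family or of the related GCACTTT was present in 18 members, held a read in 16 and lay in a cluster in 8. Of the targets listed for let-7, 13 of 22 (59.1% against 25.1%) had a cluster, including Trim71, Cdc25a, Mycn (29 reads against 0) and Igf2bp1 (46 against 0), whereas Lin28a, Cdc34 and Hmga1 had none. The let-7 seed is not among the listed ones, so these clusters could not be tied to let-7 through them, and its 8mer match CTACCTCA had 1.22 times the expected support in 3' UTRs (0.859 to 1.60). With random lists also matched on 3' UTR sites, chosen after seeing the data, the let-7 list fell just inside their central 95% range (1.56 times, percentile 97.4). Targets listed for miR-25/32/92 had clusters in 9 of 15 (60% against 20%), among them Mcl1, the signalling inhibitor Smad7 with 6 (71 against 1) and Rnf4 with 3 (21 against 0), with none in Itga5, Kat2b, Sesn3 or Itgav. A matching 7mer or 8mer was present in 14 of these genes, held a read in 10 and lay in a cluster in 4. For miR-15/16, 6 of 14 listed targets (42.9%, 17.7 to 71.1, against 23.1%) had a cluster, at percentile 94.97 of the random lists and so inside their central 95% range, among them Smad7, Cdc25a, and the cyclin genes Ccne1 (31 reads against 2) and Ccnd1 (31 against 0). Chek1, Cdc27, Fgfr1 and Smurf1 had none. The listed 7mers and 8mers in the Ccnd1 clusters were AGCACTT and GCACTTT, not the miR-15/16 match TGCTGCT. A matching 7mer or 8mer was present in 12 genes of this list, held a read in 9 and lay in a cluster in 4. The list was above the range with unmatched random lists (2.48 times) and at p under 0.01 (2.93 times). It was inside the range with random lists also matched on 3' UTR sites (1.15 times).

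Cell cycle inhibitors had clusters in 9 of 16 (56.2% against 17.5%, 3.22 times), with Cdkn1a, Btg2, Rbl2 and the kinase gene Lats1 (5 clusters, 53 reads against 0) at the top and none in Cdkn2a, Btg1, Rb1 or Cdkn2b. Of the chromatin and DNA methylation regulators, 15 of 30 (50% against 23.4%) had a cluster. Tet1, a 5-methylcytosine dioxygenase, had 10 (110 reads against 2), and the Polycomb genes Mtf2, Jarid2 and Cbx7 had 8, 7 and 5 (54 against 0, 64 against 3 and 27 against 0). Mbd3, Smarca4, Dnmt3b and Setdb1 had none. Housekeeping genes were also above their random lists, with 10 of 16 (62.5%, 35.4 to 84.8, against 28.7%), led by Actb with 15 clusters (120 reads against 6), Hsp90ab1 with 12 (95 against 4), Tubb5 with 6 (53 against 5) and Tfrc with 5 (64 against 0). Ppia, Pgk1, Sdha and Hprt had none. Ribosomal protein genes had clusters in 18 of 76 (23.7%, 14.7 to 34.8, against 32.2%, 0.736 times, percentile 5.57), among them Rpl4 (98 reads against 3), Rpl15, Rpl8 and Rplp1. This direction turned when random lists were matched on the number of predicted sites instead of expression (2.17 times, percentile 99.9).

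The lists of markers of other cell types held 5 to 8 genes each, too few for a close estimate. Clusters were present in 1 of 5 fibroblast markers (20% against 10.9%; Vim, 7 reads against 0) and in 2 of 8 neural and mesoderm markers (25% against 10.8%; Mtap2, 7 reads against 0, and Kdr, 16 against 2). They were present in 0 of 8 primitive endoderm markers (against 12.99%) and 0 of 8 trophectoderm markers (against 12.3%, exact upper limit of 36.9% for each). All 4 shares were inside the central 95% range of their random lists, and most of these genes were listed at a few FPKM or less. In all, 8 of 14 lists were above that range and 0 below it. By the share of genes with a site holding a read, also among the measures fixed in advance, 4 lists were above the range and 2 below it. Those above were the chromatin regulators (100% against 72.2%), the pluripotency factors (96% against 76.5%), the AAGUGC targets (94.7% against 69.7%) and the microRNA pathway (93.1% against 77.4%), and those below were ribosomal protein genes (59.2% against 79.3%) and neural and mesoderm markers (12.5% against 48.1%). Housekeeping genes, cell cycle inhibitors and the targets of let-7 and miR-25/32/92 were inside it by this measure. Members recur between lists (Cdc25a in 3 of them), so the lists are not independent, and the target lists come from textbook knowledge and not from this study.

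**Figure D1:**
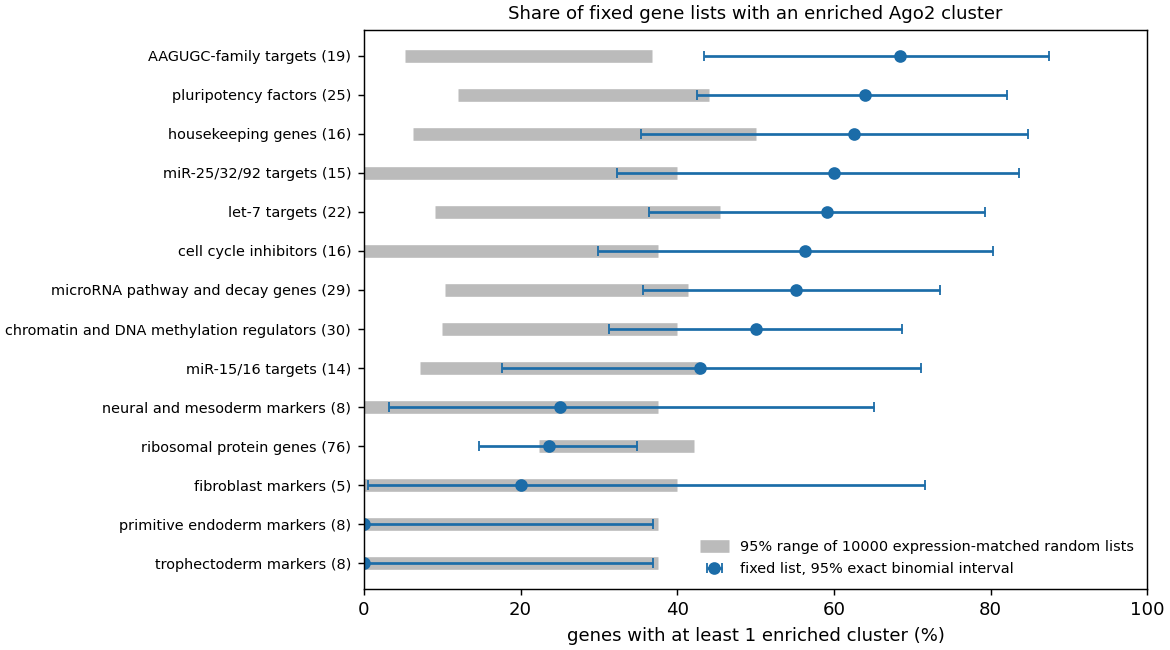
Percent of the genes of each fixed list with at least 1 enriched Ago2 cluster (points, with exact 95% binomial intervals; number of genes in brackets), over the central 95% range of 10000 random lists matched on expression (grey bars). The AAGUGC-family targets stand highest at 68.4%, and ribosomal protein genes lie at 23.7%, within their grey bar.

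The series title asks how microRNA and target levels and site affinity set the response to competing RNAs, and the predicted sites of the 50 microRNA seeds allow occupancy to be compared between seed families. Sites matching the stem cell family AAGUGC (7mers AGCACTT and GGCACTT, the seed matches of the miR-291a family and its relatives) carried reads most often over all match types: 3348 of 9738 (34.4%, gene bootstrap 32.4 to 36.3). That was 4.42 times (4.29 to 4.54) the number given by control 8mers at equal region and expression. GCGGCAC followed with 24.7% (973 of 3940, 3.07 times). TTTGCAC, the match of the miR-19 seed, had 21.8% (1848 of 8472, 2.71 times), and GCACTTT, that of the miR-17 family, had 18.2% (2745 of 15120, 2.38 times). The match of the miR-148 family, TGCACTG, had 17.1% (2674 of 15647, 2.16 times). Among 7mers and 8mers alone, GCACTTT came first, with 43.8% (5.14 times, 4.95 to 5.34) against 33.7% (4.41 times) for AAGUGC. For AAGUGC this was no higher than over all match types, so its 6mers were supported at least as often as its longer matches pooled. The largest number of supported sites, 4269 of 27093 (15.8%, 1.91 times), belonged to TGCTGCT, the match of miR-15/16. Other families with many supported sites included CCTCTGC (2993, 11.8%), GTCTTCC (2710, 11.8%), GTGCCTT of miR-124 (2571, 12.6%), ATGCTGC of the miR-103 family (2475, 14.5%), ACTGTGA of miR-27 (2434, 10.6%) and GAGCCTG (2131, 8.55%, 1.1 times). At the other end, ATGAAAA had 6.01% (0.834 times, 0.788 to 0.874), GGTTCAA 5.91% (0.838 times), AATGGAG 6.33% (0.861 times), ACACAAG 6.48% (0.916 times) and GCAAGAC 6.76% (0.933 times, 0.872 to 1.001). Of 48 families, 37 had an interval above 1, 5 below it and 6 held it. Support in control 8mers varied too: of 46 listed 8mers with at least 100 sites in 3' UTRs, 21 were above the central 95% range of 774 control 8mers and 0 below it. Counting as support only sites in an enriched cluster raised the AAGUGC family to 24.6 times control (22.8 to 26.4), and asking for at least 2 reads, chosen after seeing the data, gave 9.72 times.

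**Figure D2:**
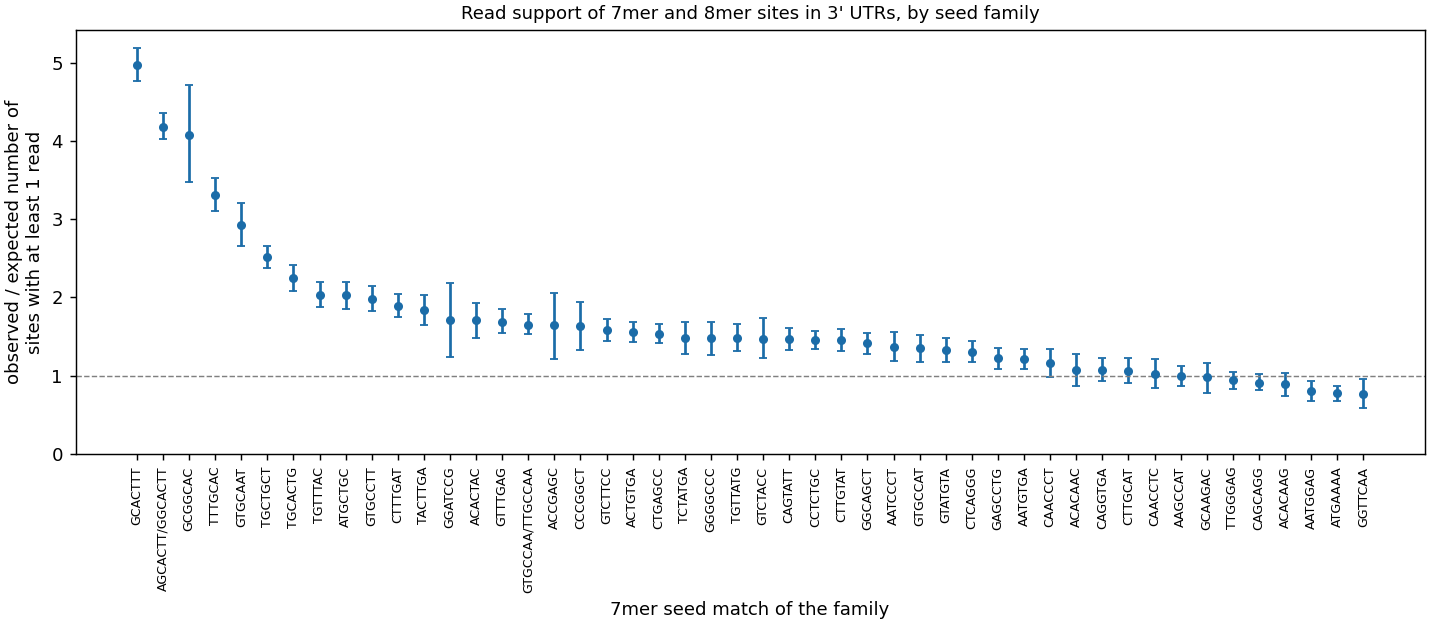
Observed over expected number of 7mer and 8mer sites in 3' UTRs with at least 1 read, for each of 48 seed families (points, with 95% intervals from resampling genes; dashed line, control 8mers at equal region and expression). GCACTTT is highest at 4.97, GGTTCAA lowest at 0.772, and 35 families have an interval above 1.

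Across the 48 families of this 1 library, which are not independent replicates, the number of sites went with the number of supported sites (Spearman rho 0.735). Supported sites are a part of the sites, so a positive value is largely built in. Weighted sites (the sum of FPKM over sites) and the supported share gave a rho of -0.113. The 5 families with the highest share, which hold an excess of supported sites by that choice, had 7.70% of the 687523 sites of listed seeds, 15.8% of the 73480 supported ones, 27.3% of the 180281 reads and 37.6% of sites in clusters. Overlapping sites of several families were counted for each family, with their reads. The AAGUGC family alone held 1.42% of sites and 10.5% of reads, rank 39 by weighted sites and rank 1 by reads, a read share 8.32 times its share of weighted sites. The same ratio was 3.53 for TTTGCAC, 3.52 for GCACTTT and 2.79 for GCGGCAC. The miR-15/16 match TGCTGCT, first by weighted sites, had a ratio of 1.12, and ATGAAAA, rank 3 by weighted sites and 20 by reads, had 0.452.

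Match length tests the affinity order of sites, from 8mer to 7mer to 6mer. The listed 7mers extend the 6mer by the base before it. A 6mer followed by A but lacking that base is therefore counted among 6mers. In 3' UTRs, 21.2% of 8mer sites carried a read (4402 of 20772, 1.82 times control, 1.78 to 1.87), 19.7% of 7mer sites (11343 of 57509, 1.69 times, 1.65 to 1.72) and 15.1% of 6mer sites (30065 of 198768, 1.29 times, 1.27 to 1.31), against 11.5% of control 8mers. The 8mer over 7mer ratio was 1.08 (1.048 to 1.11) there. In coding sequence, 8mer sites were supported 1.48 times and 7mer sites 1.62 times as often as control, a ratio of 0.912 (0.868 to 0.962). Other measures left the order there open: the ratio was 1.06 (0.794 to 1.38) for overlap with a cluster and 0.985 (0.883 to 1.096) for reads per site, and both intervals hold 1 as well as 0.912. Over all regions the ratio was 1.03 (1.0001 to 1.054) for 8mer over 7mer, with an interval that nearly reached 1, and 1.28 (1.26 to 1.30) for 7mer over 6mer. These ratios pool families that differ in support and in their mix of types. Compared within families, chosen after seeing the data, 8mer over 7mer was 1.07 (1.043 to 1.099) over all regions, 1.103 (1.07 to 1.13) in 3' UTRs and 0.988 (0.941 to 1.04) in coding sequence. Sites in an enriched cluster were spread further apart: 8mers were in a cluster 4.67 times as often as control, 7mers 3.89 times and 6mers 1.81 times. Family by family in 3' UTRs, 8mers exceeded 7mers in 27 of 48, 7mers exceeded 6mers in 39, and the full order held in 21. At 3' UTR sites with reads, the authors' log2 coverage had a median of -1.32 for 8mers, -1.41 for 7mers, -1.64 for 6mers and -1.75 for control. This value is log2 of rpm minus 0.24 times log2 of FPKM with a constant, and 1 read of 1.27 rpm sets its floor. Differences in FPKM between the types can therefore enter these medians. Among the 5 families with the highest and the 5 with the lowest share, 7mers and 8mers of GCACTTT (-0.20) and of AAGUGC (-0.42) had the highest medians.

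**Figure D3:**
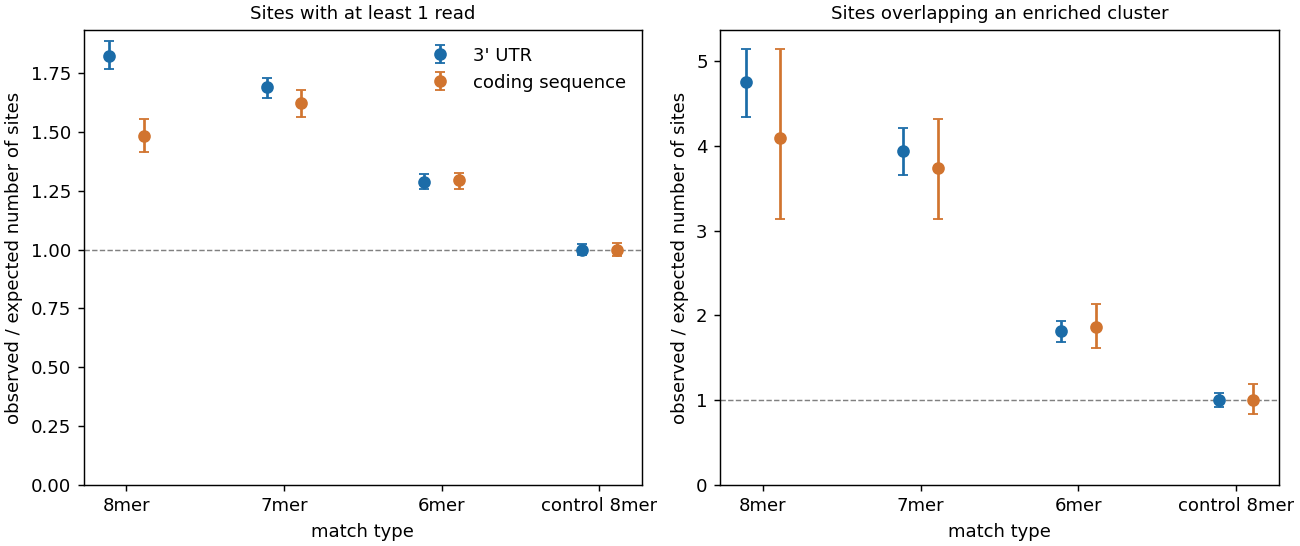
Observed over expected number of sites with at least 1 read (left) and of sites overlapping an enriched cluster (right), by match type in 3' UTRs and coding sequence (points, with 95% intervals from resampling genes; dashed line, control 8mers). In 3' UTRs the left panel falls from 1.82 for 8mers to 1.29 for 6mers and the right panel from 4.75 to 1.81.

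By region, sites of the listed seeds were supported most often in 3' UTRs (16.5% of 277049), then in coding sequence (11.5% of 186625) and 5' UTRs (10.2% of 45161). By support of at least 1 read this order was absent over 100 FPKM. Shares there were 36.7% in 5' UTRs, 34.3% in 3' UTRs and 33.2% in coding sequence (3' UTR over coding 1.03, 0.904 to 1.18). Other measures kept 3' UTRs above coding sequence in this class, 1.49 (1.135 to 1.94) for reads per site and 2.25 (1.60 to 3.23) for overlap with a cluster. At 10 to 100 FPKM 5' UTRs had 18.3% against 18.2% for coding. Pseudogenes had 1.92% and long noncoding RNAs 0.714% of 156218, of which 117406 were at 0.1 to 1 FPKM. Over control these were 1.44 times (1.202 to 1.70) and 1.39 times (1.15 to 1.69), against 1.41 times in 3' UTRs. The 3' UTR over coding ratio was 1.43 (1.39 to 1.48), and control 8mers gave 1.36 (1.32 to 1.41). Relative to control in the same region and at equal expression, 3' UTR and coding sites differed by 1.03 (0.994 to 1.06). For overlap with a cluster the 3' UTR over coding ratio was 4.41 (3.88 to 5.06) for listed seeds and 4.11 (3.43 to 5.04) for control, and with at least 2 reads the first was 2.16.

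Support rose with listed expression, from 3.62% of sites at 0.1 to 1 FPKM to 11.1% at 1 to 10, 22.5% at 10 to 100 and 32.5% over 100 FPKM, or 8.99 times (7.86 to 10.3) from the lowest to the highest. Control 8mers rose 12.0 times (10.5 to 13.9). Listed seeds relative to control went from 1.51 times (1.44 to 1.59) in the lowest class to 1.23 times (1.15 to 1.32) in the highest. By clusters the rise was 24.0 times, with at least 2 reads 17.2 times, and in 3' UTRs alone 5.10 times.

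Clusters were compared with seed matches and with copies of them displaced along the genome, which can fall in introns or past transcript ends, since the profile of the untagged library was not used here. Of 5993 clusters, 2048 (34.2%, 33.0 to 35.4) overlapped a 7mer or 8mer of a listed seed, 3.03 times the mean over 10 displacements (2.39 to 3.68 over their range). With 6mers included the count was 3175 (53.0%, 1.83 times, 1.54 to 2.20), and for 8mers alone 828 (13.8%, 3.97 times). Control 8mers gave 1.07 times (0.909 to 1.27), but those overlapping a listed site had been left out, while their displaced copies could overlap one. In 3' UTRs, 550 clusters held a 7mer or 8mer of the AAGUGC family against a displaced mean of 53.8, a ratio of 10.2. GCACTTT was in 398 against 26.6 (15.0 times), GCGGCAC in 34 against 3.1 (11 times), TTTGCAC in 184 against 20 (9.20 times), TGCTGCT in 158 against 33.5 (4.72 times) and TGCACTG in 85 against 21.5 (3.95 times). A cluster can count for several of these families. The ratios for ACTGTGA and GTCTTCC were 1.63 and 1.64.

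Supported sites of several families lay in the same transcripts. No count given by chance was made, and overlapping families can share a bound position. Among 9537 genes with a supported site, 7975 had sites of at least 2 families and 4789 of at least 5, with a median of 5. Of 1744 genes with a site in a cluster, 1288 (73.9%) had at least 2 families there and 821 at least 3. With 7mers and 8mers only, 665 of 1326 genes (50.2%) did, and 656 of 2048 clusters held at least 2 families in place of 1801 of 3175. Counting as separate only families at positions that share no base, chosen after seeing the data, 7808 genes had at least 2 supported families, and 1435 clusters, or 349 with 7mers and 8mers only, held at least 2. Mcl1 clusters held matches of 8 families, among them the AAGUGC family, GCACTTT and GTGCAAT of miR-25/32/92. Those of Cnot6 held 7 and those of Btg2 held TGCTGCT, GTGCAAT and ATGCTGC.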

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

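Tests of low-occupancy families, of the mix of families, of at least 2 reads, of the least expressed transcripts and of equal expression were chosen after the results they address were seen. The other tests were set down before. Crosslink positions and conservation were examined after the comparisons, by families ranked on these data. No biological explanation by the groups was tested, since files of 1 group were analysed, and of explanations by binding only that by offset matches to listed seeds was.

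Signal appeared in a pair of columns that the comparisons did not use. Crosslink maxima lay close to seed matches mainly in the families with the highest share, which were picked for their reads. In 1633 plus-strand clusters with a single maximum, 62.7% (58.6 to 66.7) of 582 pairs of a maximum with a 7mer or 8mer of the 5 families with the highest share were within 10 nt, with a median of 1 nt. For the other 43 families the share was 29.5% (25.9 to 33.4), and for control 8mers 12.0% (10.4 to 13.8). Control 8mers overlapping a listed site had been left out, which can lower their share near maxima that sit at listed sites. The control value is therefore not a background level. Minus-strand clusters were left out because the direction of their offsets is not given in the sources used here. Another 1426 plus-strand clusters without a single maximum were left out too. Conservation also went with reads. At 10 to 100 FPKM in 3' UTRs, 52.2% (49.5 to 55.0) of 7mers and 8mers of these 5 families with a read had a PhastCons score over 0.5, against 28.5% (25.6 to 31.6) without a read and 61.3% in clusters. Control 8mers had 38.7% with and 28.9% without, and the 5 families with the lowest share 40.9% and 34.1%.

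Some control 8mers carried as much read support in 3' UTRs as listed seeds. Counting noise was argued against by a Spearman rho of 0.456 between a pair of random sets of genes across 774 control 8mers. Of these, 54 were at 1.5 or more in the first set of genes and had 1.35 times (1.28 to 1.42) the expected support in the second, and still 1.45 times (1.252 to 1.64) at 1595 sites over 50 nt from any listed site, which argues against reads from neighbouring listed sites as the whole source. The 50 without a match to seed positions 3 to 8 of a listed family had 1.33 times (1.255 to 1.40), so such offset matches do not account for them, and all 35 control 8mers with such a match had 1.02 times (0.958 to 1.08), against 0.994 for the 739 without, although the 2 with that match to the AAGUGC family, picked from the 35, reached 2.36 times (2.0 to 2.75). Seeds of microRNAs outside the 50, binding by other proteins and uneven crosslinking remain open as untested.

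Over all regions, 8mer sites were supported little more often than 7mer sites when families were pooled, 1.03 times (1.0001 to 1.054). A different mix of families among the types accounts for a part of this, since the ratio within families was 1.07 (1.043 to 1.099) and that of coding sequence went from 0.912 to 0.988 (0.941 to 1.04), but the upper end of the first lies just under the limit set for the mix as the whole source. Dilution by families with little binding would leave those families without an order, yet in 3' UTRs the 24 families with the lower 6mer support had a ratio of 1.11 (1.04 to 1.17) with families pooled and 1.11 (1.048 to 1.17) within families, against 1.07 (1.03 to 1.11) and 1.099 (1.06 to 1.14) in the other 24. This covers 3' UTRs only, where the pooled ratio was already 1.08. The lower 24 still had 1.30 times the expected support for 8mers and 1.17 times for 7mers. The test therefore does not decide on dilution over all regions or by families with less binding. Saturation of support by 1 read in abundant transcripts cannot be told apart from a lack of order by the ratio at 0.1 to 1 FPKM, 0.977 (0.899 to 1.052), or 1.052 (0.955 to 1.15) in 3' UTRs, whose intervals hold 1 and reach past the limit set for excluding it. Over all expression levels, measures that saturate less gave higher ratios, 1.16 (1.101 to 1.23) for reads per site, 1.11 (1.07 to 1.16) for at least 2 reads and 1.201 (1.102 to 1.30) for clusters, which leaves saturation open.

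Control 8mers were supported more often in 3' UTRs than in coding sequence, 1.36 times (1.32 to 1.41). Reads spread from neighbouring listed sites are argued against as the whole source, since control sites over 50 nt away kept a ratio of 1.23 (1.15 to 1.32), though the fall leaves room for a part. Higher listed expression of genes with 3' UTR sites is argued against by the ratio at equal FPKM, 1.40 (1.36 to 1.45). Binding of Ago2 to 3' UTRs through other microRNAs, and technical differences in crosslinking or mapping between regions, were not tested.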

How the results depend on the processing

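Of 159 values under alternatives, 94 kept their place (within the interval of the reported value, within 1.5 times for counts, or on the same side of the random lists), 60 moved, 3 values of fixed lists crossed the limit of the random lists and 2 turned direction. Settings with at least 2 reads, other control sites, nested matches kept, types compared within families, families that share no base, Benjamini-Hochberg adjustment and joint matching on FPKM and 3' UTR sites were chosen after seeing the data. Unless the construction of an alternative shows it, the cause was not tested.

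With overlap with a cluster, a site wholly inside it, a cluster widened by 25 nt and a cluster of p under 0.01 as support, in that order, 8mer over control moved from 1.70 to 4.67, 5.73, 3.04 and 5.03, 8mer over 7mer from 1.03 to 1.201, 1.19, 1.22 and 1.31, and 7mer over 6mer from 1.28 to 2.14, 2.20, 1.74 and 2.15. The AAGUGC family over control moved from 4.42 to 24.6, 32.2, 13.7 and 26.6, 3' UTR over coding from 1.43 to 4.41, 4.50, 4.28 and 5.39, and the highest over the lowest expression class from 8.99 to 24.0, 22.8, 24.3 and 22.9. At least 2 reads gave 2.59, 1.11, 1.53, 9.72, 2.16 and 17.2 for these 6 values. All kept their direction.

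Sites of at least 10 FPKM gave 1.61 for 8mer over control, 1.24 for 7mer over 6mer and 3.46 for the AAGUGC family, and at least 1 FPKM gave 4.16 for the family. Every entry as listed gave 1.60, 1.201 and 4.28. In 3' UTRs alone the values were 1.82 for 8mer over control, 1.08 for 8mer over 7mer, 1.31 for 7mer over 6mer, 4.21 for the family and 5.10 for expression. Leaving out the family with the most supported sites gave 1.253 for 7mer over 6mer, nested matches kept gave 1.202, and 8mers alone gave 5.37 for the AAGUGC family. Keeping control sites that overlap a listed site gave 1.61 for 8mer over control and 4.17 for the family, and control sites over 50 nt away gave 2.19 and 5.71. Comparing types within families, in place of pooling them, gave 1.07 (1.043 to 1.099) for 8mer over 7mer. The reported interval of that ratio, 1.0001 to 1.054, nearly reaches 1, and those at 10 FPKM or more, 1.03 (0.996 to 1.067), and with overlapping control sites kept, 1.03 (0.999 to 1.053), hold it. Between 27 and 47 of 48 families had an interval above 1 under all alternatives run, against 37.

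The 3' UTR share of clusters was 68.3% of 3081 at p under 0.01, 68.3% of 3078 after Benjamini-Hochberg adjustment over the 16965 clusters that the authors' numbering reaches (fewer clusters by construction), and 55.7% after merging within 50 nt. Cluster overlap over displaced sites, 1.83, became 1.48 with clusters widened by 25 nt, 3.97 with 8mers and 3.03 with 7mers and 8mers. With 7mers and 8mers only, genes with at least 2 supported families went from 7975 to 4815 and clusters with at least 2 from 1801 to 656, as fewer sites are counted.

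Among lists, let-7 targets fell inside the random range with joint matching (1.56 times). The miR-15/16 targets rose above it with unmatched random lists (2.48 times) and at p under 0.01 (2.93 times), but not with joint matching (1.15 times). Ribosomal protein genes, 0.736 times random in the same FPKM deciles, were at 1.38 times unmatched and 2.17 times matched on predicted sites. They are listed at a median of 609 FPKM, which these alternatives do not match and the deciles match only coarsely. The other 11 lists stayed on their side of the range in the 4 alternatives run.

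No paired analysis was possible because each group has 1 library, and leaving out a library was not possible for the same reason. Not run were the 10 highest ranked microRNAs (the file has no rank), 3' UTR sites alone for the region comparison and FPKM minimums for the expression classes, which remove the classes compared. Depth limits single sites: 1 read is 1.27 rpm, most sites have none, and a cluster of 5 reads is the smallest that can pass against 0 untagged. A site without a read was not detected at this depth and is not shown to be unbound.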

Other observations

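Groups of genes chosen after seeing the data, by their symbols, were set against random lists from the same FPKM deciles. Histone genes stood out, with clusters in 21 of 35 (60.0%, 42.1 to 76.1) against 5.69% of random genes (10.5 times), at a median of 0.361 FPKM. The group was picked for its clusters, so this comparison describes it and tests nothing. The source of the FPKM values is not given in the sources used here, and most histone messages lack a poly(A) tail, so equal expression is not assured. Their 30 clusters held 334 tagged reads against 5 untagged. Hist1h3g had 3 clusters with 55 reads against 0, Hist1h4i 2 with 37 against 1, and Hist1h2bg 1 with 27 against 0 (at least 9-fold). Genes of Krüppel-like transcription factors had clusters in 10 of 15 (66.7%, 38.4 to 88.2, against 23.5%, 2.84 times), among them Klf3 with 74 reads against 1, Klf13 with 45 against 0 and Klf9 with 14 against 0. Klf2, Klf4 and Klf5 are also among the pluripotency factors. Zinc finger genes named Zfp had clusters in 64 of 318 (20.1% against 14.6%, 1.38 times). Long intergenic noncoding RNAs named linc had them in 2 of 181 (1.1%, 0.134 to 3.93, against 6.56%), linc444 with 12 clusters and linc741 with 2.

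Mitochondrial RNA held 24 clusters, 23 of them on the plus strand, with 472 tagged reads against 82 of the 1541 untagged. Of the mouse Argonaute genes, Eif2c2, the older symbol of Ago2, was listed at 18.9 FPKM and had 3 clusters with 37 reads against 2, and 0 of these clusters were in the 3' UTR. Eif2c3 was listed at 4.21 FPKM with 1 cluster of 6 reads. The series description gives human Ago2 as the single Argonaute, and the cells behind the FPKM values are not given in the sources used here, so these values do not show that the mouse genes were expressed in the lines studied.

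Also picked after their values were seen, among control 8mers with at least 100 sites in 3' UTRs, AAGCACTA had 2.45 times the expected support (47 of 164 sites), GACCCTTA 2.31 times (39 of 140), CAGCACTA 2.29 times (54 of 203), GCCCCCTA 2.13 times (supported at 26 sites) and GTACTGTA 2.0 times (93 of 373). The let-7 seed match CTACCTCA, which is not among the listed seeds, had 1.22 times (0.859 to 1.60, 35 of 255), an interval that holds 1.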
